A study of Solanum lycopersicum with 8 samples.

How the data were processed

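Total RNA from mature whole leaves and from red ripe whole fruits of 4 tomato accessions, named AV, TM, SK and RJ in the labels, was labelled with Cy3 and hybridised to 8 one-colour Agilent arrays, per the labels' protocols. Each accession gave 1 leaf array and 1 fruit array, so a tissue has 4 arrays and an accession has 2. Nothing in the labels says that a sample came from separate plants, so the 4 arrays of a tissue are 4 accessions. With accession and tissue both in the fit, p-values measure how the fruit minus leaf difference varies between these accessions, together with technical spread.

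The authors deposited 1 scanner table per array, made with Agilent Feature Extraction 10.7.3.1 per the file headers, and its processed signal is a background-corrected intensity on a linear scale. The median signal and the background signal in the same deposited tables are intensities too. The flags for outlier spots, saturation and signal well above background are yes-or-no columns of those deposited tables. The series matrix held the processed signal itself, with a largest difference of 0 from the scanner tables. The authors also deposited a normalized log2 table by probe. Differences between its arrays followed those of the log2 processed signal over 28 array pairs with a slope of 1 and a lowest correlation of 0.99989. The constants between its arrays departed by up to 0.004 log2 from a shift to the array median over all transcript spots, and by up to 0.80 log2 from a shift to the 75th percentile. Column medians of that table lay at 0 for 6 arrays, at -0.06 for TM leaf and at -0.07 for RJ leaf. Its scale and direction are settled by this comparison. The baseline subtracted from each probe stays unknown. Column medians of the series matrix were signals of 219, 147, 379 and 141 in AV, TM, SK and RJ leaf and 90.7, 60.3, 99.3 and 98.8 in the fruits in the same order.

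Each array had 45020 spots. The 35100 non-control spots held 33750 probes, of which 675 were printed on 3 spots. Values were log2 processed signals minus the 75th percentile of the array's non-control spots. Spots with an outlier flag were left out, spots of a probe were averaged, and 64 probes without a value on every array were dropped. No spot was saturated. The array design marks 8503 transcript probes as negative controls, and these were left out with the other controls. Only 153 of the 8656 spots with that mark were the designed negative-control sequence. The software's negative-control SD was therefore computed over transcripts and ran from 2270 to 9235 signal units, against 3.98 to 30.9 for the designed sequence. Between 17.3% and 24.4% of the probes of an array were flagged well above background, whereas 47.7% to 88.3% exceeded the mean plus 3 SD of the designed negative controls. By these shares the flag is a strict limit here, and a probe that misses it may still carry signal. The lowest flagged signal of an array was 0.078 to 0.165 of the software's SD, so the flag did not ask for a signal above that SD.

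Probe targets were named through their unversioned accession and the RefSeq gene table of assembly SLM_r2.1. Of the 33750 probes, 2936 matched 1214 genes, and 922 of those had a name of their own. Other targets keep the accession of the array design, and each distinct target counts as 1 gene. The gene's probe with the highest mean represented it. Of 1137 genes with several tested probes, 6 had probes called in opposite directions, none of them named, and 140 had some probes called and some not.

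Tissue was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with accession as a block, on probes well above background on at least 4 of 8 arrays. This left 5202 genes, with 3 residual and 3.89 prior degrees of freedom. Each accession was compared with the mean of the other 3 with tissue as a block, on probes well above background on at least 2 arrays, which left 6982 genes, and a moderated F-test asked for any difference among the 4. Adjusted p is Benjamini-Hochberg, with a threshold of 0.05, two-sided. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 16 lists with at least 3 tested genes, and for accessions over 80 tests of 20 lists. A single fruit or leaf has no replicate, so genes at least 2 log2 units from every other array of the tissue were counted without a test, by measured signal and, chosen after seeing the data, from the detection floor described next. Values given as "at least N-fold" set the mean of the brighter tissue against, per array of the dimmer one, the higher of the probe's own value and the lowest signal among probes well above background (the detection floor). Arrays of the dimmer tissue on which the probe was well above background keep their own value. These bounds hold for the main scaling and for the brightest probe. Other probes of the same gene can give a smaller difference.

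Groups, tests, lists and alternatives were fixed before the data were examined, apart from alternatives named as chosen after seeing the data. So was the rule for named genes. It takes the 10 largest changes in each direction among named genes past the threshold, with the same sign in 4 accessions and well above background on all 4 arrays of the brighter tissue. It adds up to 4 called members of each list, every detected gene of the carotenoid and ripening-regulator lists, the 3 highest and 3 lowest named genes per accession (by size where none passed), and the 3 largest gaps per fruit and direction. Of 120 genes planned by symbol, 81 were matched, and 4 were dropped because the match lay on another chromosome. The lists planned as patterns over gene descriptions had no description column to act on, so their members were chosen by symbol after the annotation had been seen and before any value. Light-harvesting, photosystem and Calvin cycle genes were pooled into 1 photosynthesis list for the same reason. No member was matched for viruses or transposons. Of the ripening-regulator list, 1 member enters the counts and list tests, and its own values are not reported here.

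The pairing of leaf and fruit comes from their shared accession. As a check, deviations of leaf and fruit from their tissue means were correlated across genes. The 4 same-accession values ran from -0.19 to 0.01, and no leaf correlated best with the fruit of its own accession.

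All 4 leaf arrays lay on 1 slide, the AV and TM fruits on another, and the SK and RJ fruits on the other, per the file headers. Slide was therefore fitted as a random block. A leaf-slide effect and a leaf effect share the same arrays, so only the spread between the fruit slides informs that fit.

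Alternatives were normexp background correction, quantile and median scaling, the authors' table, other filters and probe rules, a fold limit, each accession left out, and fits without the block. Normexp had been planned on the mean spot signal, and the median spot signal was used in its place. The tests were run on simulated data with 200 changed genes. For tissue, over 5202 genes, 12.0% of genes changed by 1 log2 unit were recovered, 82.0% of those changed by 2 and 98.0% of those changed by 4, with 6 false calls. In the data 51.4% of these genes were called, which makes the adjusted threshold less strict than with 200 changed genes. The simulated shares therefore do not give the sensitivity of the tissue comparison. For 1 accession against the others, over 6982 genes, 34.0% of genes changed by 2 log2 units and 94.0% of those changed by 4 were recovered, with 4 false calls. The simulated noise was normal and independent between arrays. In the data, limma gave 417, 146, 151 and 44 genes at an unadjusted p under 0.05 for AV, TM, SK and RJ, where 349 are expected by chance. These shares therefore do not give the sensitivity of the accession comparisons either. With 8 arrays, their number limits the precision.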

Results

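Transcript levels were measured in mature leaf and red ripe fruit of 4 tomato accessions, AV, TM, SK and RJ, on 8 one-colour arrays. The series addresses transcription factors of fruit ripening, in accessions described as differing in maturity and in the carotenoids of ripe fruit. Each combination of tissue and accession had 1 array, so n = 4 per tissue. The 75th percentile of the signal lay between 438 and 961 in leaf and between 191 and 293 in fruit, and 5827 to 8237 probes per array were well above background. Levels below are log2 signals relative to that percentile.

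The comparison of fruit with leaf asked which genes separate the tissues across accessions. Higher in fruit were 6 of 7 tested ripening regulators, 5 of 5 MADS-box genes, 8 of 12 ethylene genes, 4 of 4 cell wall genes, 4 of 5 aroma genes and 9 of 12 heat-shock genes, and 6 of 6 photosynthesis genes were higher in leaf. Camera called these 7 lists of 16 with its preset correlation and 0 with an estimated correlation (adjusted p = 0.2 to 0.385 for the 7). The detection filter had left 7 of 14 ripening regulators on the array, 5 of 13 MADS-box, 12 of 19 ethylene and 4 of 10 cell wall genes. It left 5 of 7 aroma, 12 of 14 heat-shock and 6 of 6 photosynthesis genes. A gene well above background in 0 leaves passed that filter only if it was so in all 4 fruits, which largely fixed its direction. RIN, TM29, MBP3, LeSEP3, NOR, AP2a, EXP1 and TBG4 passed in this way, among others. Genes dim in all 4 fruits, such as CAB6A and CAB4, passed only through leaf. The list counts above are therefore not independent of the filter. The MADS-box ripening regulator RIN rose at least 22.2-fold in fruit, to 4.70 ± 1.15 (SD, n = 4) from -1.70 ± 0.35 in leaf. Psy1, which encodes the phytoene synthase of fruit carotenoid synthesis, was above background in 2 of the 4 leaves and at least 85.2-fold higher in fruit with the main scaling (log2 6.69, SE 0.50, from the measured signals; 5.88 with normexp, under that bound of 6.41, and 6.08 without RJ). The smallest difference among the 13 tested probes of Psy1 was 4.34 log2, also under that bound. CAB4, a chlorophyll a/b-binding protein gene, was at least 150-fold higher in leaf by its brightest probe. Its 7 tested probes ran from -8.63 to -4.725 log2, the smallest less in size than its bound of 7.225. In limma, 1481 genes were higher in fruit and 1193 higher in leaf of 5202 tested, and 2602 of these 2674 had the same sign in all 4 accessions. The split depended on the scaling. The median difference over all tested genes was 0.18 with the main scaling and -0.11 with normexp, which gave 922 higher in fruit and 1341 higher in leaf. Scaling to the probes detected on all 8 arrays, chosen after seeing the data, moved the median to -0.08 and gave 1129 and 1396. Normexp with detection by the designed negative controls, chosen likewise, moved it to 0.66 and gave 7099 and 2028 of 19844.

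The 10 named genes with the largest rise in fruit were 2A11, ADH2, hdc, LOXB, AAT, Psy1, matriochka, RIN, HSP70 and ASR1. The fruit transcript 2A11 was at least 485-fold higher in fruit (adjusted p = 3.34e-06) and reached 9.14 ± 0.70. ADH2, an alcohol dehydrogenase, was at least 417-fold higher (adjusted p = 7.78e-06), and hdc was at least 72.9-fold higher. AAT and the lipoxygenase LOXB were at least 53.0-fold and 50.1-fold higher. For 2A11, ADH2, hdc, AAT and LOXB, some tested probes gave less than the bound of the brightest probe. Their smallest log2 differences were 8.80, 7.95, 3.65, 5.70 and 5.16, against bounds of 8.92, 8.705, 6.19, 5.73 and 5.65. Matriochka was at least 23.0-fold and HSP70 at least 22.2-fold higher. ASR1 was detected in both tissues and was 60.7-fold higher in fruit (log2 5.92, SE 0.32).

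The 10 named genes with the largest rise in leaf were CAB6A, TLRP, yfe37, CAB4, PsbQ, PR1b1, CYP1, PIP2-7, P69B and gad2. CAB6A was at least 140-fold higher in leaf by its brightest probe (adjusted p = 3.06e-06), but its other probe was above background in fruit and differed by -1.96 log2. TLRP was at least 138-fold, yfe37 at least 77.3-fold and the photosystem II subunit PsbQ at least 65.1-fold higher in leaf. The aquaporin PIP2-7 and the subtilisin-like protease P69B were at least 13-fold and 12.9-fold higher. The smallest log2 differences among the tested probes of yfe37 and PIP2-7 were -5.02 and -3.25, less in size than their bounds of 6.27 and 3.70. The pathogenesis-related gene PR1b1 was at least 34.9-fold higher in leaf, with fruit levels that spread widely (-0.28 ± 2.24) and were above background in 1 of the 4 fruits. CYP1 and gad2, above background in 1 and 2 of the 4 fruits, were at least 26.2-fold and 28.6-fold higher in leaf by their brightest probes. The smallest log2 differences among their tested probes were -3.45 and -3.48, less in size than these bounds of 4.71 and 4.84. With their probes averaged they differed by -4.68 and -4.61 log2, also less than the bounds, as gad2 did without AV (-4.28).

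**Figure D1:**
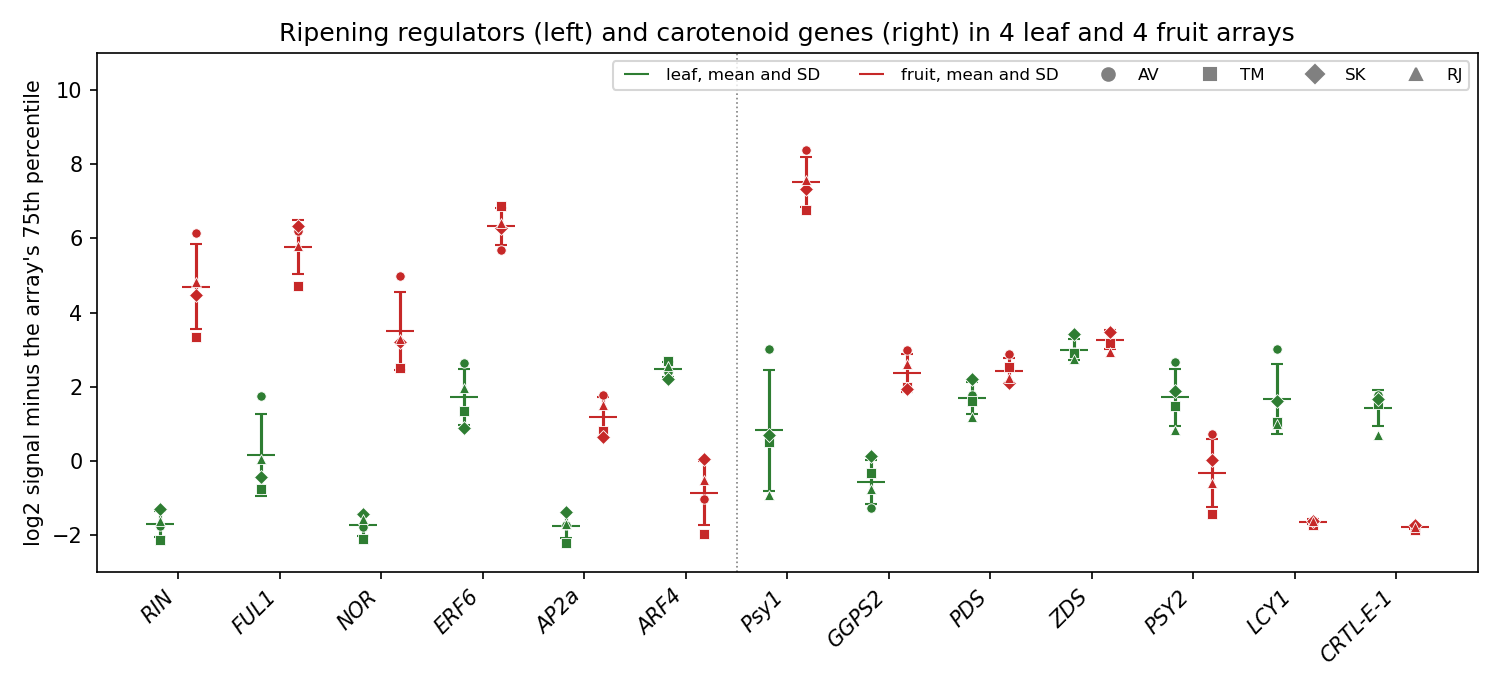
Log2 signal relative to the array's 75th percentile for 6 ripening regulators and 7 carotenoid genes, with each array as a symbol by accession and bars for the mean and SD of 4 leaf (green) and 4 fruit (red) arrays. RIN, NOR, FUL1 and Psy1 lie higher in fruit than in leaf in every accession, while LCY1 and CRTL-E-1 lie higher in leaf.

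Of the 7 tested ripening regulators, 6 rose in fruit and 1 was higher in leaf, over all genes and adjusted over the list alone (camera adjusted p = 0.0112 with the preset correlation and adjusted p = 0.2 with an estimated correlation). NOR, a NAC regulator of ripening, was at least 9.69-fold higher in fruit by its brightest probe. The smallest difference among its tested probes was 3.23 log2, under that bound of 3.28. FUL1, above background in 1 of the 4 leaves, was at least 36.0-fold higher in fruit (log2 5.17, but 4.78 with normexp and 4.995 for the smallest of its tested probes). ERF6 rose by 4.61 (SE 0.45) on the log2 scale. AP2a was at least 1.95-fold higher in fruit, whereas ARF4 was at least 4.15-fold higher in leaf. All 5 tested MADS-box genes rose in fruit, including RIN and FUL1 from the previous list, TM29 (at least 4.18-fold), MBP3 (at least 2.97-fold) and LeSEP3 (at least 1.99-fold). The MADS list had a camera adjusted p = 0.00299, and adjusted p = 0.2 with an estimated correlation. All 3 tested NAC genes, of 5 on the array, were higher in fruit, NOR, JA2 (at least 3.72-fold) and NAM1 (log2 0.84, SE 0.29). NAC1 of the ripening-regulator list, not tested, was above background in 2 leaves and 0 fruits. The NAC list itself did not pass camera (adjusted p = 0.0595). It passed with normexp (0.042) and quantile scaling (0.0485), but not there with an estimated correlation (adjusted p = 0.44 and 0.47). With normexp and detection by the designed negative controls, chosen after seeing the data, 5 were tested and camera gave an adjusted p = 0.242. The call of NAM1 was lost with normexp and with quantile scaling (adjusted p = 0.337 and 0.117) and without any 1 accession (adjusted p = 0.0833 to 0.114). Adjusted over the list alone, the MADS and NAC counts were the same.

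Carotenoid and precursor genes moved apart. Of 10 tested, 2 were higher in fruit, 4 were higher in leaf and 4 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.716). The list had 17 genes on the array. HDS, GGPS1, NSY, CrtR-b1, CrtR-b2, VDE and CYP97A29 missed the detection filter. ZISO, CRTISO, ZEP and CYP97C11 had no match, so the tested genes are a part of the pathway. The camera direction was leaf although the list's median and mean were both 0.18, as was the median of all genes. Beside Psy1, GGPS2, a geranylgeranyl diphosphate synthase, was at least 4.46-fold higher in fruit. The lycopene cyclases LCY1 (beta) and CRTL-E-1 (epsilon) were at least 2.39-fold and 2.01-fold higher in leaf. PSY2 was at least 2.36-fold higher in leaf, though 1 of its other probes was above background in fruit, and DXR was at least 1.57-fold higher, a call lost without any 1 accession (adjusted p = 0.0606 to 0.13). The log2 differences of PDS, DXS, ZDS and HDR were 0.74, 0.42, 0.26 and 0.10, none past the threshold. Of the 6 tested probes of DXS, which ran from 0.42 to 0.93, some did pass. ZDS and HDR changed sign under other scalings, and HDR passed with its probes averaged (log2 0.85, adjusted p = 0.0372). PDS passed with slide as a random block (adjusted p = 0.0181), with no replicate block (0.0478) and without SK (0.04).

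Ethylene genes were higher in fruit for 8 of 12 members, and ACO4 was higher in leaf (log2 -3.56). By their brightest probes ACO1, EIN2 and EIL4 did not pass (log2 2.52, 0.45 and 0.30). Some tested probes of ACO1 (2.52 to 3.105) and of EIL4 (0.30 to 1.42) did pass. The ethylene list had a camera adjusted p = 0.0112, and adjusted p = 0.2 with an estimated correlation. Adjusted over the list alone, 9 were higher in fruit. With normexp and detection by the designed negative controls, chosen after seeing the data, the ethylene list had an adjusted p = 0.362 and the cell wall list 0.068. The ACC synthases ACS2 and ACS4 were at least 7.89-fold and 4.35-fold higher, and the receptors ETR3 and ETR4 at least 10.5-fold and 7.20-fold. All 4 tested cell wall genes, of 10 on the array, rose, EXP1 (at least 15.4-fold), Cel2 (log2 5.32, SE 0.43), XTH5 and TBG4 (at least 1.81-fold). XTH5, above background in 1 of the 4 leaves, rose at least 10.8-fold (log2 3.43, but 3.16 with normexp). The cell wall list had a camera adjusted p = 0.00648, and adjusted p = 0.208 with an estimated correlation. PG2, PE1, PME2.1 and Man4, well above background in 3 fruits each and not in TM fruit, missed the filter of 4 arrays. Of 5 aroma genes, 4 rose, namely ADH2, LOXB, AAT and LOX1.1 (at least 2.60-fold), with a camera adjusted p = 0.00648 and adjusted p = 0.385 with an estimated correlation. The counts of the cell wall and aroma lists did not differ when adjusted over the list alone.

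Heat-shock genes, listed as signs of stress, were higher in fruit for 9 of 12 members. HSP21 was at least 15.2-fold, MTSHP at least 13.8-fold and HSP70 at least 22.2-fold higher. The smallest difference among the 4 tested probes of MTSHP was 3.17 log2, less than its bound of 3.78. HSP17-6, above background in 1 of the 4 leaves, was at least 31.2-fold higher (log2 4.96, but 4.37 with normexp). HSFA3 was at least 2.21-fold higher in leaf. The list had a camera adjusted p = 0.00299, and adjusted p = 0.2 with an estimated correlation. All 6 photosynthesis genes were higher in leaf, among them CAB6A, CAB4, PsbQ and the Calvin cycle enzyme SBPASE (at least 8.30-fold). This list had the lowest camera adjusted p, 8.60e-05, and adjusted p = 0.2 with an estimated correlation. For both lists the counts adjusted over the list alone were equal to those over all genes.

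**Figure D2:**
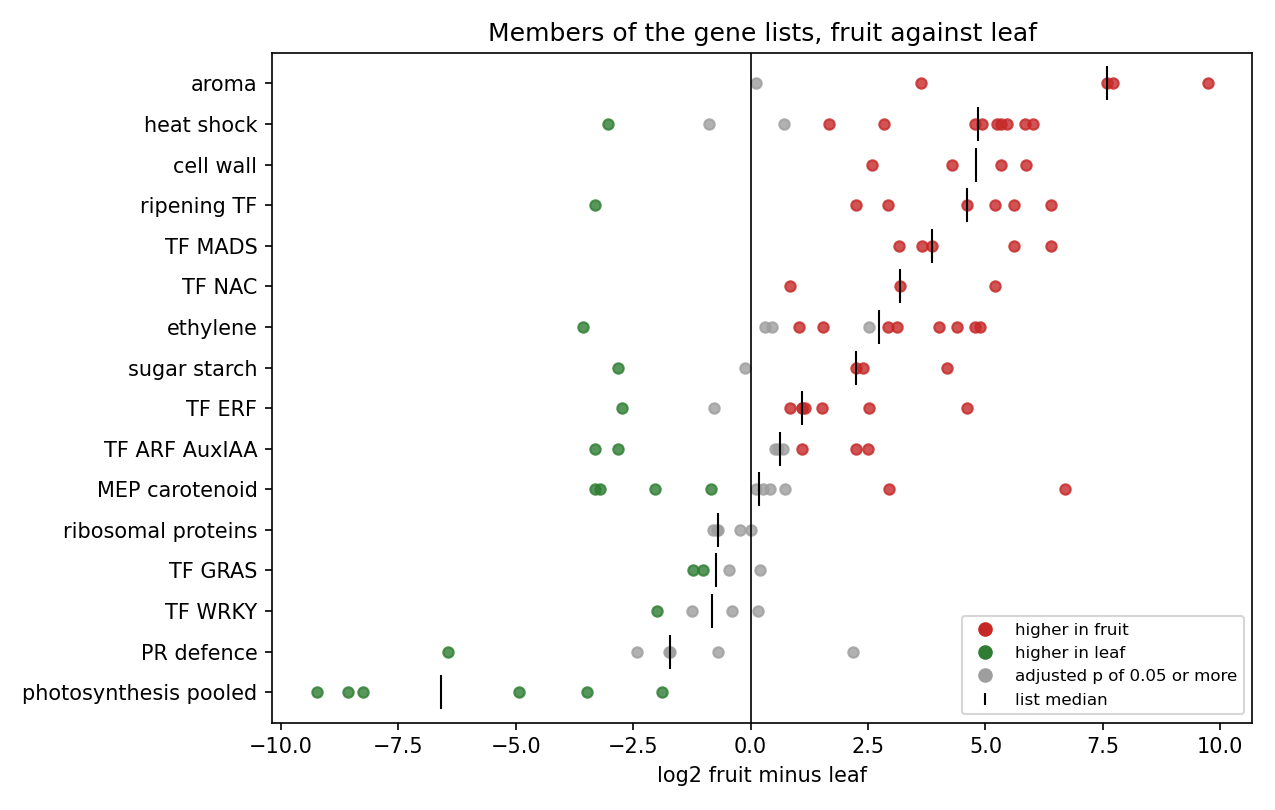
Log2 fruit minus leaf of each tested member (points) of the 16 gene lists with at least 3 tested members, red when higher in fruit, green when higher in leaf and grey when not past the threshold, with the list median as a bar. Photosynthesis genes all lie on the leaf side, with a median of -6.59. Cell wall and MADS genes all lie on the fruit side, with medians of 4.80 and 3.87. These medians are of measured signals, with members not well above background in the dimmer tissue included, so they are not bounds.

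The remaining lists did not pass camera. With normexp and detection by the designed negative controls, WRKY, GRAS, ribosomal protein and defence genes did (adjusted p = 0.0236, 0.00945, 0.0133 and 0.0203). So did the proteinase inhibitors, of which 4 were tested there (adjusted p = 0.0195). The direction of each was leaf. Camera sets a list against the other genes, and the median of all genes there was 0.66 toward fruit. A list without a change of its own can therefore be called toward leaf. With an estimated correlation these lists had, in the same order, adjusted p = 0.628, 0.478, 0.389, 0.629 and 0.584. Sugar and starch genes had 3 of 5 higher in fruit, the acid invertase AI (log2 4.19, SE 0.34), sus3 and SPS, and AgpL1 was higher in leaf (adjusted p = 0.436). Of 9 ERF genes 6 were higher in fruit, JERF1 by 2.51 (SE 0.32) and ERF-E5, above background in 1 of the 4 leaves, by at least 2.23-fold (log2 1.15, but 1.01 with normexp and 1.08 without AV), while ERF4 was at least 1.65-fold higher in leaf (adjusted p = 0.238). Of 8 ARF and Aux/IAA genes 3 were higher in fruit, among them ARF5, and 2 in leaf, ARF4 and IAA16 (adjusted p = 0.597). GRAS genes had 2 of 4 higher in leaf, GAI and GRAS6 (adjusted p = 0.309), and WRKY genes 1 of 4, WRKY40, with the same sign in 3 accessions (adjusted p = 0.409). Defence genes had 1 of 6 higher in leaf, PR1b1 (adjusted p = 0.27), and 0 of 5 ribosomal protein genes passed in limma (adjusted p = 0.312), with 0 also adjusted over the list alone. For the other lists of this paragraph these counts were the same adjusted over the list alone, except that 2 ERF genes were then higher in leaf. The calls of GAI without SK (adjusted p = 0.0541), GRAS6 and ERF-E5 without TM or RJ (0.0986 and 0.128, 0.053 and 0.0502) and WRKY40 without TM, SK or RJ (0.0848 to 0.0965) were lost, as were those of GRAS6 with no replicate block (0.0783) and ERF-E5 with normexp (0.0598). With the main filter, smaller lists were counted only. VAHOX1 was higher in fruit and T12 in leaf among 2 homeobox genes, vsf-1 was the 1 of 2 bZIP genes higher in fruit, ZF2 the 1 of 2 zinc finger genes and CCD1B the 1 of 2 carotenoid cleavage genes. The proteinase inhibitors ARPI (at least 4.29-fold) and CPI (at least 2.84-fold) were both higher in leaf. Flavonoid, bHLH and histone or cell cycle genes had 0 called of 1, 1 and 2 tested. The pollen marker LAT61 was higher in fruit (log2 1.1, adjusted p = 0.0388; 0.186 with normexp, 0.0788 with median centring and 0.0792 in the authors' table), and the seed marker LEA14 did not pass (log2 0.14, SE 0.70). Without TM, SK or RJ the calls of T12 and CCD1B were lost (adjusted p = 0.0535 to 0.141 and 0.0663 to 0.0812), and without AV, TM or SK that of LAT61 (0.0538 to 0.143). The call of T12 was also lost with its probes averaged (log2 -0.69, adjusted p = 0.104). MYB, glandular trichome, root and chlorophyll breakdown lists had 0 tested genes.

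The accession comparisons asked which genes distinguish 1 accession from the mean of the other 3 in both tissues. No gene passed. AI stood 2.26 (SE 0.41) higher in AV than in the others (adjusted p = 0.589), by 2.02 in leaf and 2.50 in fruit. The chalcone synthase genes CHS1 and CHS2 stood 2.39 (SE 0.74) and 1.81 (SE 0.62) higher in SK (adjusted p = 0.993 for both), and CHS2 stood at -2.16 (SE 0.62) in TM. CHS1 was well above background on 1 of the 6 arrays of the other accessions and CHS2 was not in TM fruit, so these are differences of measured signals, and CHS1 in SK leaf lay at least 1.73 log2 above the nearest other leaf. By size, since none passed, the named genes highest in AV were CIP1 (2.75), PR1b1 (2.63, with 0.91 in leaf and 4.35 in fruit) and AI. No other fruit was well above background for PR1b1, and AV fruit lay at least 2.56 log2 above the nearest. The lowest in AV, by their mean, were XTH3 (-6.03 in leaf and -0.53 in fruit), tXET-B2 (-5.89 and -0.52) and ICL (-2.09 and -3.78), differences of measured signals. AV leaf was not well above background for XTH3 and tXET-B2, which lay at least 3.18 and 2.98 log2 below the nearest other leaf, nor was AV for ICL in either tissue. ICL was highest in TM (0.97 in leaf and 3.39 in fruit), followed by TCP3 (0.73 and 2.31) and GLB2 (0.05 and 2.92). No other fruit was well above background for TCP3. From the detection floor TM fruit lay 1.20 log2 above the nearest (0.89 with normexp). ACO1 and CHI9 were among the lowest in TM by their mean but had opposite signs in the tissues, 0.63 and 0.78 in leaf and -3.86 and -3.67 in fruit, where CHI9 was not well above background. RSI-1 was the other high gene of SK, and CIP1, pip1 and VAHOX1 were its lowest. GluB (0.32 in leaf and 3.49 in fruit), ZF2 (2.88 and 0.58) and WRKY41 were highest in RJ, and AI (-0.98), CPN21 and sumo lowest. TM and SK fruit lay under the detection floor for GluB, as did AV leaf for ZF2 and WRKY41, so these are differences of measured signals. Limma called 0 of 6982 genes in each of the 4 contrasts, with 417, 146, 151 and 44 genes at an unadjusted p under 0.05 for AV, TM, SK and RJ, where 349 are expected by chance. The F-test for any difference called 0 genes, with 179 at an unadjusted p under 0.05. Leaving out AV brought 1 call, the unnamed target AI780188, higher in SK by 5.48 (adjusted p = 0.0236).

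Among gene lists by accession, camera with the preset correlation called 10 of 80 tests, and none with an estimated correlation (adjusted p = 0.625 to 0.707 for these 10). By the preset correlation, the carotenoid list was lower in RJ (median -0.44, adjusted p = 5.28e-04) and higher in AV (median 0.35, adjusted p = 0.014), with adjusted p = 0.625 and 0.707 with an estimated correlation. The leaf medians were -0.70 in RJ and 0.55 in AV, and the fruit medians -0.01 and 0.25. Sugar and starch genes and MADS genes were higher in AV and GRAS genes lower by the preset correlation alone. Cell wall and MADS genes were lower in TM and GRAS genes higher. Ethylene genes were lower and histone or cell cycle genes higher in SK. These 8 calls had adjusted p = 0.625 with an estimated correlation.

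Fruits of single accessions were set side by side without a test, since each had 1 array. Of 8 cell wall list genes well above background in at least 1 fruit, PG2, PE1, PME2.1 and Man4 were lowest in TM fruit and not well above background there. EXP1 (4.59) and Cel2 (7.56) were highest in TM fruit, and 2 lay between. The polygalacturonase gene PG2 was at -1.64 in TM fruit, not well above background, against 5.80 to 9.03 in the other fruits, a gap of at least 44.0-fold to the nearest. The pectinesterase genes PE1 and PME2.1 were at least 24.9-fold and 5.93-fold below the nearest other fruit, and with normexp the measured gap of PE1 was 4.47 log2, less than that bound of 4.64. AV fruit stood out by high TSI-1 (at least 12.2-fold above the next fruit), the endo-mannanase gene Man4 (31.0-fold) and the hexose transporter gene HT2 (at least 5.12-fold), and by low SNF4 (at least 7.79-fold or log2 2.96 below, but 2.76 with normexp). By measured signal, AV fruit had 109 genes at least 2 log2 units above and 47 below every other fruit, TM fruit 4 and 31, SK fruit 15 and 7, and RJ fruit 3 and 1. With signals not well above background set at the array's detection floor, chosen after seeing the data, the counts were 39 and 20, 2 and 13, 7 and 0, and 2 and 0. With normexp both directions together gave 98 genes in AV, 13 in TM and 9 in SK.

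**Figure D3:**
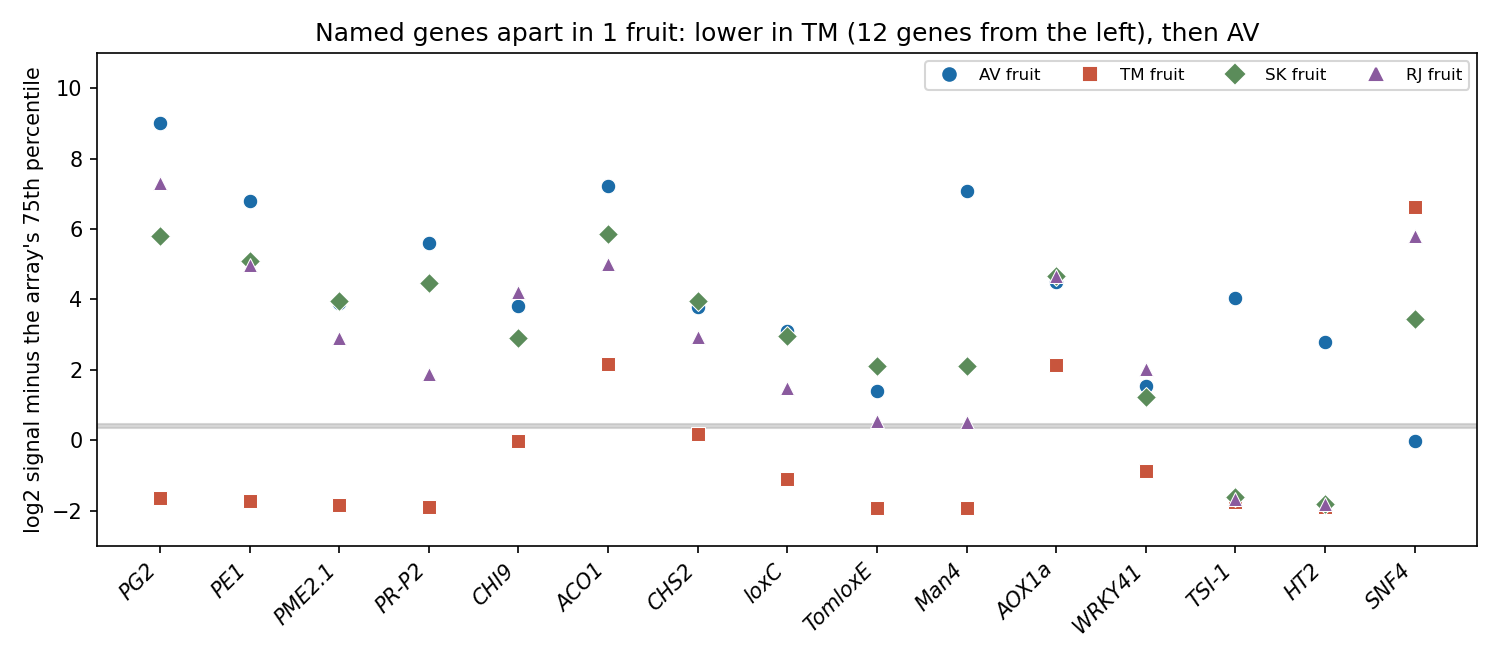
Log2 signal relative to the array's 75th percentile in the 4 fruits, 1 array each, for the 12 named genes lowest in TM fruit by at least 2 log2 units of measured signal, followed by 3 genes apart in AV fruit, with the band of the lowest signals well above background in grey. PG2, PE1 and PME2.1 lie under the band in TM fruit, at -1.64, -1.72 and -1.85.

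The other named genes of the rule lay closer to the next fruit. In AV, ICL and LHA1 were lower. In TM, TAS14 was 2.61-fold above the next fruit, with GAL83 and TCP3 behind it. SK fruit had MTA 4.09-fold above the next, then CYP1 and SAMDC, and SEND33, CIP1 and ftsH6 below. RJ fruit had GluB, ER24 and XYL1 above and DDTFR8, AI and APX1 below, none by 2 log2 units. Among ripening regulators, RIN was 6.14 in AV fruit, 4.84 in RJ, 4.46 in SK and 3.35 in TM. NOR was 4.98 in AV and 2.50 in TM, and Psy1 8.38 in AV and 6.76 in TM. ERF6 was 6.89 in TM, 6.41 in RJ, 6.29 in SK and 5.70 in AV. FUL1 was highest in SK (6.32) and lowest in TM (4.73), and AP2a was highest in AV (1.77) and lowest in SK (0.65).

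The fruit minus leaf differences of single accessions were alike across 5202 genes, which are not independent replicates. Pearson correlations between accessions ran from 0.77 (AV and TM) to 0.96 (TM and RJ), and the 3 pairs with AV had 0.77, 0.84 and 0.80. AV leaf correlated with the other leaves at 0.79 to 0.80, whereas TM, SK and RJ leaf correlated with each other at 0.88 to 0.97.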

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

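Of the tests below, those of diluted fruit RNA and of ripening state in TM fruit, and those of fruit RNA and of measurement noise in AV leaf, were chosen only after the result was seen, as were all counts from the detection floor, the lowest signal among an array's probes well above background.

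The count of genes that separate the tissues was compared with other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes as the tissues did, the tissue split itself. With so few splits that share cannot fall below 1 in 35. A random grouping of the arrays is thus argued against but not excluded. The tissue split also parts the leaf slide from the fruit slides, so a slide effect is not addressed. Without the accession block the tissue split called 2934 genes, and the highest of the other splits called 7. Among the 8 splits that part all 4 accession pairs, the tissue split called 2674 with the block and the others at most 0. That share cannot fall below 1 in 8, so these 8 splits alone decide nothing. Every other split puts leaves and fruits in the same group, so the tissue difference widens its spread and lowers its count.

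By measured signal, TM fruit lay at least 2 log2 units below every other fruit for 31 genes, 12 of them named, 10 of which were not well above background there. With such signals set at the array's detection floor, the gap was still that large for 13 genes, 7 of them named. The 12 include PG2, PE1 and PME2.1 and, chosen after their values were seen, the ethylene-forming ACO1 (2.17 against 5.01 to 7.22), CHS2, the chitinase CHI9, and loxC and Man4 with gaps of at least 1.14 and 0.17. Dilution of the fruit RNA by other RNA is argued against, since the median difference of TM from the other fruits was -0.17 over 151 genes high in the other fruits and dim in their leaves. A sequence variant under single probes is argued against too, since 100% of the 32 other probes of 13 of these genes were equally low by measured signal and 59.4% from the floor. An earlier ripening state stays open. Of the 6 regulators raised in fruit, 4 (RIN, FUL1, NOR and AP2a) were lower in TM fruit than the mean of the other fruits. AP2a was lowest in SK fruit (0.65, against 0.81 in TM), and ERF6 was higher in TM fruit than that mean. A difference between accessions is likewise open, and with 1 fruit array per accession neither can be told apart from the sample.

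AV leaf lay apart from every other leaf by at least 2 log2 units of measured signal for 432 genes. Of these, 186 were higher and 246 lower, with 66 and 113 from the floor. By measured signal, the named genes with the largest gaps were EXP2, AMT1-2 and CIP1 above and XTH3, tXET-B2 and PMEU1 below. From the floor, the largest gaps above were those of CIP1 (2.92), BMY3 (2.91) and mcpi (2.64), while EXP2 and AMT1-2 had 1.71 and 1.12. Fruit RNA in the leaf sample is argued against, since 7.04% of 199 genes bright in the other fruits and dim in the other leaves were well above background in AV leaf, and 0 of the 10 brightest. Measurement noise stays open, since of the 150 other probes of 87 of these genes 93.3% lay equally far apart by measured signal but 33.3% from the floor, and the rest have no such probes. An earlier comparison rested on 3 spike-in transcripts, whose spread was 0.118 of that of the genes in AV leaf and 0.09 to 0.183 in the other leaves, and decided nothing. An accession difference shared by both tissues is argued against as the whole source, since 57.2% of the 201 genes detected in fruit, and 60% of the 125 detected in all 4 fruits, deviated the same way in AV fruit. An accession difference specific to leaf, and the age or handling of the leaf, were not tested and stay open.

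Of 112 groups of 4 arrays examined, 5 held an array far from the other 3, where chance gives about 5.60. AV leaf was far from the other leaves for CPI (2.43 against 1.71 to 1.78), ERF4 (2.76 against 0.48 to 0.75) and HSP17-6 (-0.65 against 0.08 to 0.14). For HSP17-6 the AV, SK and RJ leaves lay under their detection floors, so that distance is between weak signals. SK leaf was far below the others for PR1b1 (3.73 against 6.85 to 7.05), and TM fruit was below the other fruits for T12 (1.97 against 2.78 to 2.87).

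The tissue difference took opposite directions between accessions for the defence list and for LEA14, and these differences were not tested. The median fruit minus leaf of the defence list was 1.13 in AV, -4.70 in TM, -1.04 in SK and -1.86 in RJ. These are medians of measured signals. In TM fruit all 6 tested defence genes lay under the detection floor of 0.34, so the size of -4.70 is uncertain. For LEA14 the difference was 2.85 in AV, -1.15 in TM and -1.56 in RJ, and SK had 3.87 in leaf and 4.28 in fruit. The 4 fruits lay between 3.81 and 4.32 for LEA14, and AV leaf lay at 1.47 against 3.87 to 5.37 in the other leaves.

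Transcript probes that the design marks as negative controls carried signal outside the comparisons. Of the 8503, 1695 exceeded the mean plus 3 SD of the designed negative controls on all 8 arrays, and 277 were well above background on all 8.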

How the results depend on the processing

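The alternatives that set detection by the designed negative controls, kept the marked transcript probes, scaled to the probes detected on all 8 arrays, set weak signals at the detection floor or joined another scaling with an estimated correlation were chosen after seeing the data. The count of 2674 tissue genes became 5306 with no filter on dim probes and 786 with probes well above background on all 8 arrays, where 23675 and 2313 genes were tested. It became 9127 with normexp and detection by the designed negative controls, where 19844 genes were tested and 77.8% of those called were higher in fruit. Without 1 replicate, that is 1 accession in both tissues (replicate 1 is AV), it ran from 2079 to 2899. With no replicate block it was 2934, with 46 calls lost and 306 gained, 4 and 17 of them of named genes. Among the 73 genes followed below, GRAS6 then lost its call (adjusted p = 0.0783) and PDS gained one (adjusted p = 0.0478). With slide as a random block it was 3448, with 0 calls lost and 774 gained, at an estimated slide correlation of -0.222. PDS then gained a call (adjusted p = 0.0181), as it did without replicate 3 (0.04). Each slide holds 1 tissue, so that fit cannot remove a leaf-slide effect. The added calls do not strengthen the tissue result. The series matrix repeats the main values by construction.

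The 7 tissue lists past camera were 0 with a correlation estimated from the residuals, alone or with normexp (under both filters) or quantile scaling, 10 with fry, which asks another question, and 7 without any 1 replicate. The 10 accession list calls were 0 with an estimated correlation and 6 with quantile normalization. Accession counts were 0 in every setting, except 1 gene for SK without replicate 1 (a range of 0 to 1). Genes apart in 1 fruit were 98 for AV, 13 for TM and 9 for SK with normexp. With a limit of 1 log2 unit they were 391, 259, 120 and 15 for AV, TM, SK and RJ, and with 3 units 77 for AV, 11 for TM and 5 for SK. From the detection floor they were 59, 15, 7 and 2 for AV, TM, SK and RJ, by construction fewer. The cause of the normexp and quantile changes was not tested.

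Of 1329 values for 73 named tissue genes, 1270 kept direction and side of the threshold, 41 lost the call, 25 of these without 1 replicate (NAM1, DXR, LAT61, WRKY40, T12, CCD1B, ERF-E5, GRAS6 and GAI, with fewer arrays), 4 gained it and 14 reversed, none of them called in the main setting. HDR reversed to -0.44 with normexp (also with detection by the designed controls), -0.26 with quantile, -0.003 with median centring, -0.002 in the authors' table and -0.16 with the probes detected on all 8 arrays. ZDS reversed to -0.024 with normexp under both filters and -0.001 with those probes. LEA14 reversed to -0.21 with normexp under both filters, -0.14 with quantile, -0.13 with those probes and -0.77 without replicate 1, with 0.70 as the highest value without 1 replicate. The cause was not tested. All 414 values of 24 accession genes kept direction and side, and of 240 values for fruit gaps 217 moved by less than the spread of the other fruits. The 75th percentile of the signal was 191 to 293 in fruit and 438 to 961 in leaf, and 6378 to 6734 probes of a fruit and 5827 to 8237 of a leaf were well above background.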

Other observations

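Several named genes, PR1b1 and CHI3 of the defence list among them, stood above the other fruits in AV fruit, and all were chosen after their values were seen. Of the other tested defence genes, PR-P2 and CHI17 were highest in AV fruit by less than 2 log2 units. GluB and CHI9 were higher in RJ fruit (3.59 and 4.21) than in AV fruit (2.245 and 3.82). PR1b1 was 2.98 in AV fruit against -1.79 to -0.61 in the others, none of them well above background, and so at least 2.56 log2 above the next. The chitinase gene CHI3 was 5.14 against -1.10 to 1.07. By measured signal 19 named genes were at least 2 log2 units above every other fruit in AV, and 9 with signals not well above background set at the detection floor.

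Named regulators stood apart in AV leaf in both directions, and those given here were also chosen after their values were seen, with no list or test. AV leaf was not well above background for 5 that were low. CBF1 was at least 2.98 log2, GRAS4 at least 2.64, MPK3 at least 1.97, WRKY41 at least 1.81 and ZF2 at least 1.20 below every other leaf. In the same leaf, Psy1 was 3.03 against -0.92 to 0.70, and the chloroplast regulator GLK1 was at least 2.06 above the other leaves, none of them well above background. ERF4 was 2.76 against 0.48 to 0.75, and GLK2 was at least 0.11 above the other leaves, again none of them well above background. By measured signal, 17 named genes were above and 26 below every other leaf by at least 2 log2 units, and 10 and 13 were from the detection floor. No explanation was tested for these groups.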
